A study of Homo sapiens with 6 samples.

How the data were processed

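Poly(A)-selected RNA was sequenced from 6 libraries of CFPAC1 cells, 3 pools of wild-type clones and 3 pools of clones labelled IRF1-KO. The deposited table holds whole-number counts per gene, and its columns have the layout that featureCounts writes, per the file headers. Per the submitters' processing notes, featureCounts 0.6.1 and edgeR 3.2.2 were used with the GRCh38 (hg38) genome build. The aligner, the gene annotation and the strand setting of the counting are not given in the sources used here. The gene coordinates printed are the lowest start and highest end of the exons in the file. Samples of other cell lines and of interferon treatment named in the series description were not analysed here. The labels do not say whether the clone pools were grown and processed on separate occasions, so p-values measure the spread between these pools.

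The table listed 19402 genes, of which 19363 are protein-coding in GENCODE 29, and none of its count columns lacked a sample. Symbols for 19342 gene identifiers came from a table of current names, 56 more came from GENCODE 29 and 4 identifiers had none. Total counts ranged from 16413682 to 28258075 per library. Within groups, chi-square values per degree of freedom between libraries lay between 27.0 and 57.6, so no pair of libraries agreed within sampling noise. GC content was taken from the longest protein-coding transcript of each gene in GENCODE 29 and was found for 13387 of 13388 tested genes.

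Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, scaled by TMM factors, and fitted with robust dispersion and the quasi-likelihood F test (estimateDisp, glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors of log2 fold changes are those implied by the F statistic. A fold is the antilog of the fitted log2 fold change, and CPM are TMM-scaled. Fixed lists with at least 5 tested members were tested on log2 CPM (prior count 2) with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, each adjusted over 26 lists.

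The gene lists covered antiviral interferon-stimulated genes, interferon-gamma-induced genes, MHC class I, MHC class II, NF-kappaB-driven inflammation, glycolysis, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, lipid transport and storage, the respiratory chain, the tricarboxylic acid cycle, ATF4 and amino acids, NRF2 and the pentose phosphate pathway, hypoxia, lysosomes, classical and basal-like pancreatic cancer, epithelial identity, mesenchymal genes, proliferation, p53 targets, leukocytes, endothelium, acinar and islet cells, mitochondrially encoded transcripts and replication histones. Some genes stand in more than 1 list. The lists, the tests and the rule for named genes were fixed before the data were examined. Named were IRF1; genes past the threshold with a mean of at least 2 CPM in the higher group and no overlap of CPM between groups, up to 12 with the largest rise and 12 with the largest fall; and for each list up to 4 members past the threshold with the smallest adjusted p, or else the member with the smallest p.

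Several named genes overlap others in the file: PSMB9 overlaps PSMB8 and TAP1, PSME1 overlaps EMC9, PSME2 overlaps RNF31, ERAP1 overlaps CAST and SF3A2 overlaps PLEKHJ1, all on the opposite strand. ALDOA and OSGIN1 each overlap a gene on the same strand. As the strand setting is not given, reads of such pairs cannot be told apart where exons overlap, and values of these genes are uncertain to that extent, as are those of HLA and histone genes with near-identical copies.

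The procedure was tested on simulated counts drawn for the real genes, over 13281 genes. The means and library sizes were those of the IRF1-KO against WT comparison. The 200 changed genes were drawn only from genes with a mean over 5 CPM. The quasi-likelihood test recovered 10% of genes changed 1.5-fold, 62% at 2-fold, 96% at 4-fold and 100% at 8-fold, 50 genes each, with 10 false calls. DESeq2 recovered 26%, 76%, 98% and 100%, with 43 false calls. These simulated counts had no trend with GC content. Alternatives were RLE and upper-quartile factors, no filter and a stricter filter on low counts (at least 5 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library in turn, and stricter thresholds. A correction for GC content, added after the data were examined, subtracted a natural spline with 5 degrees of freedom of each library's log2 deviation on GC content as an offset in the same edgeR fit. In further simulated counts a GC trend was added, alike in every IRF1-KO library. There unchanged genes over 65% GC had a median log2 fold change of 0.50, and edgeR made 24 false calls. With the correction these were 0.03 and 9.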

Results

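Gene expression was measured by sequencing of poly(A)-selected RNA from CFPAC1, a human pancreatic ductal adenocarcinoma cell line. The 6 libraries came from 3 pools of wild-type clones (WT) and 3 pools of clones labelled as deleted for IRF1 by CRISPR-Cas9 (IRF1-KO). IRF1 is a transcription factor induced by interferon that drives genes of antiviral defence and antigen presentation. Total counts were 18642377, 18394715 and 21003927 in WT replicates 1 to 3 and 16413682, 28258075 and 26323782 in IRF1-KO replicates 1 to 3. Of 19402 genes in the table, 13388 were counted deeply enough to be tested. The comparison asked which genes, among them interferon and metabolic genes, differed between clone pools labelled IRF1-KO and WT pools.

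The IRF1 transcript was not lower in the libraries labelled IRF1-KO. IRF1 (ENSG00000125347.14; GRCh38 chromosome 5, 132481609 to 132490777, minus strand) had 87.3, 91.3 and 82.6 CPM (counts scaled to the size of the library) in WT replicates 1 to 3 and 117, 123 and 132 CPM in IRF1-KO replicates 1 to 3. The group means were 87.1 ± 4.35 CPM in WT and 124 ± 7.52 CPM in IRF1-KO (SD, n = 3 each). The log2 fold change was 0.51 ± 0.10 (SE), with every IRF1-KO library above every WT library, and the difference was not past the threshold (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.135). DESeq2 gave the same gene a log2 fold change of 0.52 with an adjusted p of 0.00105, and the adjusted p ranged from 0.00105 to 0.451 over the 14 alternatives. A small insertion or deletion made by Cas9 need not lower a transcript counted over all exons, so these counts do not check the knockout, and directions below are those of the libraries labelled IRF1-KO.

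Genes of interferon response and antigen processing fell in the libraries labelled IRF1-KO. PLAAT4, an interferon- and retinoid-inducible phospholipase, dropped 32.7-fold, from 347 ± 119 CPM in WT to 10.6 ± 0.691 CPM in IRF1-KO (SD, n = 3 each; log2 fold change −5.03 ± 0.30, SE). The interferon-inducible GTPase gene GBP4 was 9.15-fold lower (log2 fold change −3.19 ± 0.26), and UBA7, which encodes the activating enzyme for the ubiquitin-like protein ISG15, was 8.75-fold lower (−3.13 ± 0.24). RTP4, an interferon-induced gene, fell 7.33-fold (−2.87 ± 0.30). PSMB9, a catalytic subunit of the immunoproteasome, fell 6.13-fold from 43.1 ± 4.62 to 6.97 ± 2.19 CPM (SD, n = 3 each; −2.61 ± 0.24, SE).

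The remaining named falls were between 2.08-fold and 4.73-fold. APOL6 and APOL1, members of the apolipoprotein L family, were 4.73-fold and 4.59-fold lower, and TLR3, the endosomal sensor of double-stranded RNA, was 3.61-fold lower. ERAP2, an aminopeptidase that trims peptides for MHC class I, was 3.35-fold lower. IL15RA, the interleukin-15 receptor alpha chain, fell 3.24-fold, GBP3 fell 2.63-fold and PARP14 fell 2.48-fold. PSME1 and PSME2, the subunits of the interferon-inducible proteasome activator, fell by the same 2.08-fold, from 222 ± 7.89 to 107 ± 5.97 CPM and from 228 ± 11.7 to 110 ± 5.99 CPM (SD, n = 3 each). ERAP1, which was outside the rule for named genes and is given after its values were seen, was also past the threshold. Its log2 fold change was −0.92 ± 0.10 (SE). ERAP1 lost the call without any 1 of the libraries except WT replicate 3, and with the replicate number as a block.

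In all, 17 of 13388 genes were past an adjusted p of 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), 15 lower and 2 higher, and 16 of these differed by at least 2-fold. At an unadjusted p of 0.05, 502 genes were lower and 721 were higher, 1223 of 13388 in all, against 669 if no gene differed. The count depended on single libraries. It was 5 without WT replicate 2, 91 without WT replicate 3, 3 without IRF1-KO replicate 1 and 3 without IRF1-KO replicate 3. DESeq2 called 332 genes, 203 higher and 129 lower, with all 17 among them. PLAAT4 and UBA7 were past the threshold in all 14 alternatives, and the 16 named genes past the threshold kept their direction in all 14. Each of the other 14 named genes lost the call without at least 1 of the 6 libraries. APOL1 also lost it with upper-quartile factors (−2.16, adjusted p = 0.0567). With the replicate number as a block, RTP4, IL15RA, CDT1, SF3A2 and APOL1 lost it, at adjusted p from 0.0509 to 0.0865.

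**Figure D1:**
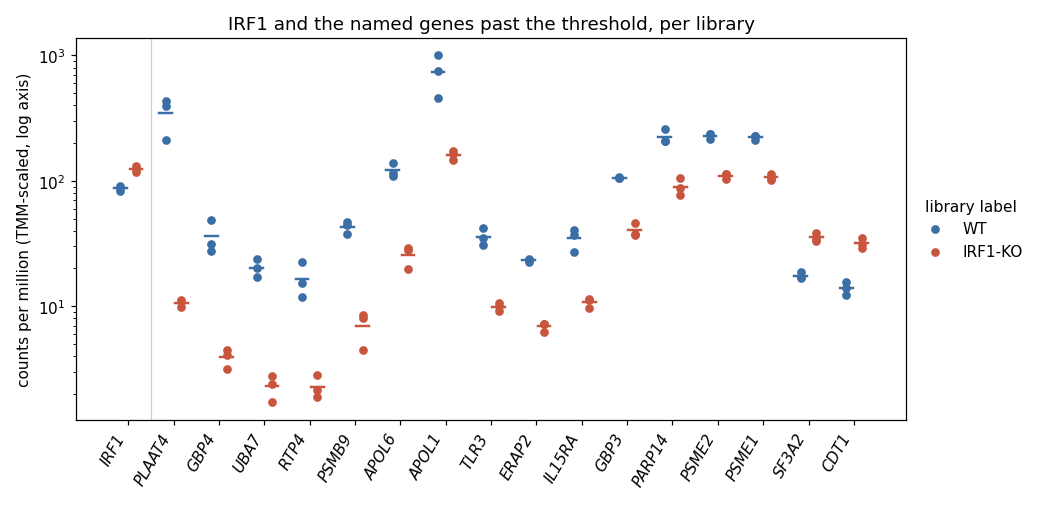
Scaled counts (CPM) of IRF1 and of the 16 named genes past the threshold, on a log axis, in 3 WT (blue) and 3 IRF1-KO (red) libraries; each point is 1 library and each bar the group mean. IRF1 lay at 82.6 to 91.3 CPM in WT and at 117 to 132 CPM in IRF1-KO, and PLAAT4 had means of 347 and 10.6 CPM.

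Both genes that rose have GC-rich transcripts. CDT1, which licenses replication origins, rose 2.28-fold from 13.9 ± 1.57 CPM in WT to 31.7 ± 2.79 CPM in IRF1-KO (SD, n = 3 each; log2 fold change 1.19 ± 0.14, SE). SF3A2, a splicing factor subunit, rose 2.02-fold from 17.5 ± 1.12 to 35.3 ± 2.52 CPM (1.01 ± 0.12). Transcript GC content was 64.9% for CDT1 and 66.6% for SF3A2, against a median of 48.5% over tested genes. The 477 tested genes over 65% GC had a median log2 fold change of 0.52, and genes under 50% GC had one of −0.04. Libraries differed along the same axis within groups: genes over 65% GC deviated from their means by a median of −0.59 log2 CPM in WT replicate 1, −0.13 in WT replicate 2 and −0.10 in WT replicate 3. In IRF1-KO replicates 1 to 3 the deviations were 0.10, 0.46 and 0.31. With a correction for GC content, chosen after this trend was seen, no gene was higher at an adjusted p under 0.05 and 13 were lower (edgeR quasi-likelihood, Benjamini-Hochberg). It brought the median of the genes over 65% GC to −0.00319. The correction removes any group difference that follows GC content, technical or biological, so the lost calls cannot tell these apart. Of the genes that fell, PARP14 (−1.27 ± 0.17, adjusted p = 0.0859) and APOL1 (−2.11 ± 0.25, adjusted p = 0.0509) lost the call with it. In the fit with this correction 589 genes were higher at an unadjusted p of 0.05. No gene was higher without WT replicate 2 or without any 1 of the IRF1-KO libraries, whereas 55 were higher without WT replicate 3. Those 55 genes had a median GC content of 64.6%, as did the 203 genes that DESeq2 called higher.

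**Figure D2:**
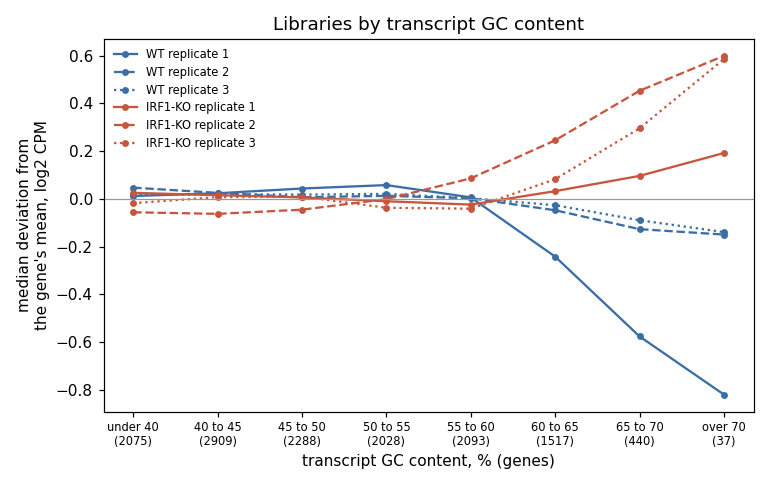
Median deviation of each library from the gene's mean over the 6 libraries, in log2 CPM, for tested genes in 8 classes of transcript GC content in percent, with the number of genes in each class; lines are single WT (blue) and IRF1-KO (red) libraries. Libraries stayed near 0 below 60% GC and spread above it, from −0.82 in WT replicate 1 to 0.60 in IRF1-KO replicate 2 in the class over 70% GC.

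Of the 15 genes that fell, 12 were members of 3 interferon and MHC class I lists fixed before the data were examined. The lists held 108 of the 13388 tested genes (Fisher's exact test, two-sided, p = 1.81e-23, with genes treated as independent). PLAAT4, RTP4 and TLR3 were outside these lists. Without WT replicates 1, 2 and 3 in turn, 17, 3 and 19 members were past the threshold, beside 22, 5 and 36 lower genes. Without IRF1-KO replicates 1, 2 and 3 in turn they were 2, 10 and 2, beside 3, 12 and 3. Of 36 tested interferon-gamma-induced genes, 35 had a negative log2 fold change (median −1.19), and 7 were past the threshold over all genes, among them UBA7, APOL6, GBP4 and GBP3; 24 were lower when adjusted over the list alone. The camera adjusted p was 1.34e-29 at the preset correlation, and with an estimated correlation the adjusted p was 0.146. Of 22 genes of MHC class I processing and presentation, 19 had negative values (median −1.05). In that list 5 were past the threshold over all genes, including ERAP2, PSMB9, PSME1 and PSME2, and 19 were lower when adjusted over the list alone (camera adjusted p = 3.03e-24; adjusted p = 0.146 with an estimated correlation). All 53 antiviral interferon-stimulated genes were tested, 52 with negative values (median −0.97), 1 past the threshold (PARP14) and 42 lower when adjusted over the list alone (camera adjusted p = 4.96e-34; adjusted p = 0.326 with an estimated correlation). In these 3 lists 77 of 108 distinct genes were lower in every IRF1-KO library than in every WT library, as were 904 (6.75%) of all 13388 tested genes. The MHC class II list, with 12 tested genes, had a median of −0.90 and no gene past the threshold over all genes; 2 were lower when adjusted over the list alone (camera adjusted p = 7.81e-06; adjusted p = 0.586 with an estimated correlation). At an unadjusted p of 0.05, 6 of its genes were lower, and DESeq2 called 2. The median of the list was −0.50 without WT replicate 1. Its member with the smallest p was HLA-DOB (log2 fold change −1.04 ± 0.23, SE, adjusted p = 0.179 with edgeR quasi-likelihood and Benjamini-Hochberg). HLA-DOB reads can be shared with related HLA genes and its value is uncertain.

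With camera at its preset correlation, 11 of 26 lists were past an adjusted p of 0.05. In the other groupings of the 6 libraries into 3 and 3, the same test called 6 to 15 lists. A call at this setting is thus weak evidence by itself. Estimated correlations were 0.62 for the interferon-stimulated, 0.20 for the interferon-gamma and 0.27 for the MHC class I list, against the preset 0.01. With an estimated correlation no list was called, and 3 lists were at an unadjusted p under 0.05. The directional fry test called 3 lists, the interferon-gamma list (adjusted p = 0.0142), MHC class I (adjusted p = 0.014) and hypoxia (adjusted p = 0.036). The mixed fry test, which takes changes of members in either direction, called 6 lists. It added the interferon-stimulated (adjusted p = 0.0297), glycolysis (adjusted p = 0.0158) and endothelial lists (adjusted p = 0.0152).

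**Figure D3:**
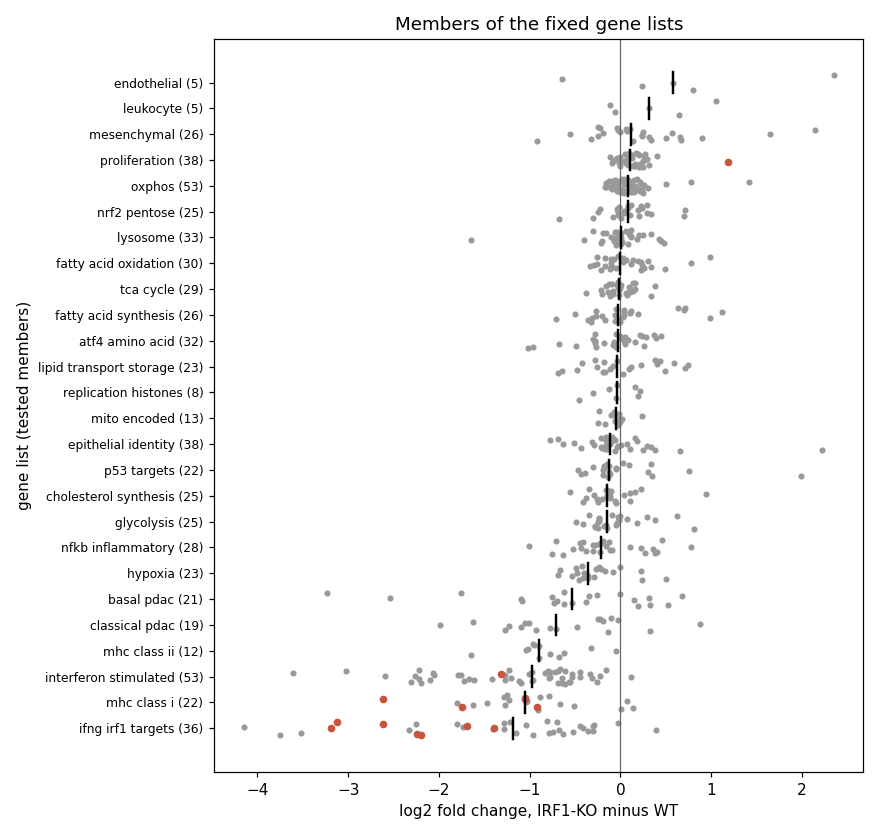
Log2 fold change (IRF1-KO minus WT) of the tested members of 26 fixed gene lists, with the number of tested members in brackets; each point is 1 gene, red where past an adjusted p of 0.05 over all genes and grey otherwise, and black bars are medians. The interferon-gamma, MHC class I and interferon-stimulated lists had the lowest medians, at −1.19, −1.05 and −0.97.

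HIF target genes were lower as a list, by less than the interferon genes. Of 23 tested hypoxia genes, 20 had negative values with a median log2 fold change of −0.36 (camera adjusted p = 0.000346 at the preset correlation; adjusted p = 0.162 with an estimated correlation). None was past the threshold over all genes with edgeR, 6 were lower at an unadjusted p of 0.05, DESeq2 called 1, and 1 was lower when adjusted over the list alone. NDRG1, a stress- and hypoxia-induced gene, had the smallest p, with a log2 fold change of −0.67 ± 0.14 (SE).

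Genes of the classical subtype of pancreatic cancer had a median of −0.71 over 19 tested members, 17 of them negative (camera adjusted p = 0.0459; adjusted p = 0.738 with an estimated correlation). Computed from log2 CPM, the scale on which camera was run, the median was −0.19 for this list and −0.34 for the inflammatory list below. The mucin gene MUC13 had the smallest p in this list, at −1.99 ± 0.56 (SE). Basal-like genes had a median of −0.54 over 21 members and were not called (adjusted p = 0.0915), with S100A2 at −0.75 ± 0.16 and 1 member lower when adjusted over the list alone. NF-kappaB-driven inflammatory genes had a median of −0.22 over 28 members (adjusted p = 0.0264; adjusted p = 0.881 with an estimated correlation), with TNFAIP3 at −0.72 ± 0.27, and at −0.47 without IRF1-KO replicate 3. No member of these 3 lists was past the threshold over all genes with edgeR; of 68 distinct genes, 7 were lower at an unadjusted p of 0.05 and DESeq2 called 1. The classical list was not called without WT replicate 2 (median −0.30) or without IRF1-KO replicate 1 (−0.66) or 3 (−0.67). It was also not called with no filter on low counts (median −0.54, camera adjusted p = 0.0842) or with the stricter filter (−0.24, camera adjusted p = 0.588). The inflammatory list had a median of −0.51 without IRF1-KO replicate 2, was not called without WT replicate 3 (−0.13) and turned direction without IRF1-KO replicate 3 (camera direction up, median −0.0168).

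Metabolic lists showed small medians and no member past the threshold over all genes with edgeR. Of 128 distinct genes in the 5 lists, 13 were higher and 5 lower at an unadjusted p of 0.05, and DESeq2 called 6. Glycolysis had a median log2 fold change of −0.15 over 25 genes (camera adjusted p = 0.412), although the aldolase gene ALDOA had a value of 0.81 ± 0.13 (SE) and was the 1 member higher when adjusted over the list alone. Cholesterol synthesis had a median of −0.14 over 25 genes (adjusted p = 0.45), with CYP51A1 at −0.42 ± 0.17. Fatty acid synthesis had a median of −0.02 over 26 genes (adjusted p = 0.954), with AGPAT2, whose transcript is 65.9% GC, at 0.99 ± 0.24 and at 0.57 ± 0.19 after the GC correction. Fatty acid oxidation was at −0.00112 over 30 genes (adjusted p = 0.578), with ECI1 at 0.78 ± 0.20. The lipid transport and storage list had a median of −0.04 over 23 genes (adjusted p = 0.488). In it PLIN2, a lipid droplet coat protein, had a value of 0.75 ± 0.16 and was the 1 member higher when adjusted over the list alone. For these last 3 lists the camera direction was up, and their medians computed from log2 CPM were −0.00241, 0.0287 and 0.00237.

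Mitochondrial and stress lists also had no member past the threshold over all genes with edgeR; of 169 distinct genes, 9 were higher and 2 lower at an unadjusted p of 0.05, and DESeq2 called 4. The tricarboxylic acid cycle list had a median of −0.02 over 29 genes (camera adjusted p = 0.933), with ACO1 at 0.34 ± 0.16 (SE), and at 0.22 without WT replicate 2 or without IRF1-KO replicate 1. Respiratory chain genes had a median of 0.08 over 53 genes (adjusted p = 0.0267; adjusted p = 0.881 with an estimated correlation), with NDUFS7, whose transcript is 64.9% GC, at 1.41 ± 0.28 and 2 members higher when adjusted over the list alone. That list was not called without WT replicate 1 (median 0.07), WT replicate 2 (0.05), IRF1-KO replicate 1 (0.08) or IRF1-KO replicate 3 (0.00275), and its median was 0.12 without WT replicate 3. The ATF4 and amino acid list had a median of −0.03 over 32 genes (adjusted p = 0.757), with SLC7A5 at 0.45 ± 0.14. NRF2 and pentose phosphate genes had a median of 0.08 over 25 genes (adjusted p = 0.315), with OSGIN1 at 0.71 ± 0.28, and at 0.47 after the GC correction. Without WT replicate 3, OSGIN1 (1.14, adjusted p = 0.0446), NDUFS7 (1.76, adjusted p = 0.0409) and CTSS (−1.95, adjusted p = 0.0409) were past the threshold over all genes. Lysosomal genes had a median of 0.00120 over 33 genes (adjusted p = 0.836), and CTSS, which is also in the MHC class II list, stood at −1.65 ± 0.40.

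S phase and mitosis genes had a median log2 fold change of 0.11 over 38 genes (camera adjusted p = 0.00581; adjusted p = 0.881 with an estimated correlation), with 1 member, CDT1, past the threshold over all genes and when adjusted over the list alone. This list was not called without IRF1-KO replicate 1 (median 0.07), had a median of 0.25 without WT replicate 1 and 0.17 without IRF1-KO replicate 2, and turned direction without WT replicate 2 (−0.0250). The p53 target list had a median of −0.13 over 22 genes (adjusted p = 0.717), with BBC3 at 1.99 ± 0.61 (SE). BBC3 counts were low, with means of 0.314 ± 0.218 CPM in WT and 1.24 ± 0.572 CPM in IRF1-KO (SD). Epithelial genes had a median of −0.12 over 38 genes (adjusted p = 0.717), with CLDN3 at 2.22 ± 0.61, which DESeq2 called (adjusted p = 0.0170). CLDN3 had 1.04, 1.74 and 1.01 CPM in WT and 1.59, 7.23 and 8.73 CPM in IRF1-KO replicates 1 to 3. IRF1-KO replicate 1 thus lay within the WT range. The transcripts of BBC3 and CLDN3 are 69.7% and 69.2% GC, and their values after the GC correction were 1.22 ± 0.52 and 1.42 ± 0.54.

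Among markers of other cell types, the mesenchymal list had a median of 0.12 over 26 genes (camera adjusted p = 0.0264; adjusted p = 0.738 with an estimated correlation), with MMP2 at 1.65 ± 0.46 (SE), which DESeq2 called (adjusted p = 0.0329). It was not called without WT replicate 1 (median 0.16), WT replicate 2 (0.11) or IRF1-KO replicate 1 (0.15), and its median was 0.50 without WT replicate 3, 0.19 without IRF1-KO replicate 2, 0.21 without IRF1-KO replicate 3 and 0.25 with no filter on low counts. The endothelial list had 5 tested members and a median of 0.58 (adjusted p = 0.0314; adjusted p = 0.326 with an estimated correlation), with TIE1 at 0.432 ± 0.339 CPM in WT and 2.25 ± 0.646 CPM in IRF1-KO (SD) and 1 member higher when adjusted over the list alone. It was not called without WT replicate 1 (median 0.52) or IRF1-KO replicate 3 (0.54), or with no filter on low counts (0.59, camera adjusted p = 0.0893). After the GC correction neither list was called (camera adjusted p = 0.0528 for both), with a median of 0.15 for the mesenchymal and 0.26 for the endothelial list. Leukocyte markers had a median of 0.31 over 5 tested members (adjusted p = 0.306), with LAPTM5 at 1.05 ± 0.44. Of 20 acinar and islet markers in the table only CHGB was tested, at 0.43 ± 0.51, and at 0.14 without WT replicate 2, 1.00 without WT replicate 3, 0.78 without IRF1-KO replicate 2 and 0.16 without IRF1-KO replicate 3. Mitochondrially encoded transcripts had a median of −0.05 over 13 genes (adjusted p = 0.542), with MT-CO1 at −0.25 ± 0.10, and made up 4.12% to 4.81% of the counts of each library. Replication-dependent histone genes had a median of −0.04 over 8 genes, and of 0.0356 computed from log2 CPM (camera direction up, adjusted p = 0.899). The smallest p in that list belonged to H2BC21, at −0.30 ± 0.24 and at 0.0105 without WT replicate 2, whose reads can be shared with other histone genes.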

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

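The GC correction was chosen after the data were examined; the other alternatives were planned. All 14 alternatives of the gene test kept IRF1 above 0 and the 16 called named genes in their direction. Against 17 genes changed (2 higher, 15 lower), the counts were 31 (5 and 26) with no filter on low counts, where more genes were tested, 332 (203 and 129) with DESeq2, and 7 (0 and 7) at an adjusted p under 0.01. DESeq2 also made 43 false calls in simulated counts. The higher count alone moved with the stricter filter (4) and with the GC correction (0), which lowered CDT1 to 0.80 ± 0.17 and SF3A2 to 0.49 ± 0.13 (log2, SE). With the replicate block 31 genes were called (4 higher, 27 lower), 11 of them shared with the 17. Same-numbered libraries had deviations from their group means correlated at −0.02, 0.25 and 0.06, and differently numbered ones at −0.30 to 0.25. Not every library correlated best with its own number. So few values do not settle whether the numbers pair the libraries. The block moved the median of the classical list from −0.71 to −0.22 and of the inflammatory list from −0.22 to −0.33. Without 1 library, 3 to 91 genes were called (0 to 55 higher, 3 to 36 lower), 3 to 16 of the 16 called named genes, IRF1 at 0.47 to 0.58, and 7 to 14 lists. Against 11 lists, 0 were called with an estimated correlation, 3 with directional fry and 6 with mixed fry. IRF1 passed the threshold with DESeq2 (0.52). Direction reversed for H2BC21 (0.0105) and the proliferation list (median −0.0250) without WT replicate 2, and for the inflammatory list without IRF1-KO replicate 3 (camera direction up, median −0.0168). Without 1 library H2BC21 ranged from −0.43 to 0.0105, the proliferation median from −0.0250 to 0.25 and the inflammatory median from −0.51 to −0.0168. Where no cause is given, the cause was not tested. In simulated counts of this depth and number of pools, 62% of 2-fold changes and 10% of 1.5-fold changes were recovered. These shares are for 200 changed genes with means over 5 CPM and need not carry over to the real data. There APOL3 (13.5-fold lower, adjusted p = 0.0616) and TRIM22 (8.13-fold lower, adjusted p = 0.0695) missed the threshold with edgeR quasi-likelihood. Both were picked after their values were seen.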

Other observations

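The genes just short of the threshold named here were chosen after their values were seen. At adjusted p between 0.05 and 0.1 (edgeR quasi-likelihood, Benjamini-Hochberg) 18 genes had negative log2 fold changes, 10 of them in the interferon and MHC class I lists, and 11 had positive ones. The inflammatory caspase CASP1 was at −3.52 ± 0.48 (SE) and the related CARD16 at −3.22 ± 0.42, with WT means of 4.17 and 2.78 CPM. APOL3 was at −3.76 ± 0.51, TRIM22 at −3.02 ± 0.44, IFIT3 at −2.22 ± 0.30 and SAMD9L at −2.07 ± 0.29. LGALS9, which encodes galectin-9, was at −1.84 ± 0.28, and B2M, the light chain of MHC class I, was at −0.91 ± 0.15 with means of 2121 CPM in WT and 1127 CPM in IRF1-KO. PKMYT1, H2AX, MBD3 and MZT2B were among the positive genes, at 1.10 ± 0.14, 1.39 ± 0.19, 1.39 ± 0.20 and 2.57 ± 0.38. The positive genes had a median GC content of 64.9% and the negative ones of 44.9%.

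Interferon ligand transcripts were scarce in both groups. IFNB1 had 0 to 2 counts per library and IFNG had 0 counts in all 6, whereas IFNE had 32, 82 and 44 counts in WT replicates 1 to 3 and 14, 38 and 53 in IRF1-KO replicates 1 to 3. These counts are not scaled to the library totals, which were highest in IRF1-KO replicates 2 and 3. The members of the MHC class I list named next were also chosen after their values were seen. CALR, CANX and PDIA3, general chaperones of the endoplasmic reticulum, were its 3 members without a negative value, at 0.00490, 0.14 and 0.07, whereas TAPBP and TAPBPL, chaperones dedicated to peptide loading, were at −0.79 ± 0.19 and −1.25 ± 0.21.

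In the paragraphs below, the test of GC-rich genes within groups, the test of swapped labels and the medians of lists in other splits were chosen after the result was seen. The first pattern was the rise of GC-rich genes. A copy-number gain was not borne out for the rise as a whole. Genes over 65% GC had a median log2 fold change above 0.2 on 12 of the 12 chromosomes with at least 10 such genes. The medians ran from 0.204 on chromosome 14 (10 genes) to 0.808 on chromosome 16 (50 genes). Chromosome 16 holds CDT1 and also ALDOA, ECI1, SLC7A5, OSGIN1 and MMP2, named above for different lists, and PKMYT1. All of these had positive values, whereas PSMB10 of the MHC class I list, on the same chromosome, was at −1.03. A gain of chromosome 16 on top of the shared rise was not tested and stays open. A library GC-content bias may account for the rise, since libraries of one group differed in these genes by up to 0.883 times the difference between the groups. The GC correction ended both calls by lowering the fold changes and raising their errors, from 1.19 ± 0.14 to 0.80 ± 0.17 for CDT1 and from 1.01 ± 0.12 to 0.49 ± 0.13 for SF3A2 (SE). Differences between clone pools, or the genotype itself, stay open for the rise, since all IRF1-KO libraries lay above all WT libraries in these genes.

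The second pattern was the fall of interferon and MHC class I genes. A GC trend did not account for it: after the GC correction the 108 members of the 3 lists had a median log2 fold change of −0.98 ± 0.10 (bootstrap SE). The bootstrap here and below resampled genes as if independent. Its errors are a spread between genes, not between clone pools. The fall did not rest on one library, as the median nearest 0 over the 6 fits without 1 library was −0.92 ± 0.10, although single calls depended on libraries. The genotype given by the labels and other differences between the clone pools stay open, and no test here separates them. The same median computed from log2 CPM was −0.98 in the real grouping and at most 0.71 in size in the 9 other groupings of 3 and 3.

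The third pattern was the higher IRF1 transcript in the libraries labelled IRF1-KO. It was not removed by the GC correction, which gave a log2 fold change of 0.59 ± 0.10 (SE). A gain of the locus was not borne out, with a median of −0.0107 ± 0.0458 (bootstrap SE) over 18 tested genes within 1 Mb. If loss of IRF1 lowers interferon-gamma-induced genes, exchanged group labels would place them higher in the libraries labelled IRF1-KO. Their median was −1.19 ± 0.23 (bootstrap SE). Since genotype and other differences between the clone pools were not separated for this fall, the test cannot exclude exchanged labels. A transcript that is edited and still made stays open as a biological explanation and was not tested, since reads over the targeted site were not analysed here.

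Only 10 groupings of the 6 libraries into 3 and 3 exist, too few for a share under 0.05. The real grouping gave 17 genes changed and the highest other gave 1, so 1 of 10 was as large. As the sides of the other groupings have no fixed order, the counts in one direction, 15 lower and 2 higher, were compared with the larger of the higher and lower counts in each other grouping, at most 1 (a lower gene), so 1 of 10 was as large for each. For lists called with camera at the preset correlation the real grouping gave 11 and the highest other 15, and 3 of 10 gave as many. Among the lists, hypoxia had a median of −0.36 in the real grouping and at most 0.15 in size in the others, and the p53 target list, which was not called, had −0.12 against 0.0466, while the classical list had −0.19 against 0.80 and MHC class II −0.96 against 1.03, computed from log2 CPM.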
